A study of Mus musculus with 4 samples.

How the data were processed

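Liver total RNA from ABCA1-transgenic mice was measured on oligonucleotide arrays, with 1 biotin-labelled array for each of 4 biological replicates. Per the labels' protocols, male C57BL/6 mice of 5 to 6 months were fed the NIH36 diet, livers were snap-frozen, and RNA was extracted with Trizol and cleaned on columns with DNase. Per the labels' protocols, 2 ug of total RNA was amplified with the RiboAmp procedure. RiboAmp is a linear RNA amplification that starts at the poly(A) tail, so signals come mainly from the 3-prime part of transcripts. The labels put all 4 samples in 1 group. The series design names wild-type controls, and no wild-type array was analysed here, so the transgenic against wild-type comparison could not be made. The labels call the samples biological replicates and do not say more about the animals. They are taken as 1 animal each and called mouse 1 to mouse 4 here, after the replicate number in the sample titles.

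The deposited values are 1 signal intensity per probe set and array and on a linear scale. The submitters' processing notes name RMA, without a version. The deposited intensities differ from usual RMA output in 3 ways. They are linear, they reach down to 0.1, and the sorted log2 values of the arrays differ by up to 1.17. The mean after trimming 2% at each end was 1000 on every array. How background was treated and how probes were combined is not given in the sources used here, and no detection calls were used. Low signals are therefore kept as deposited, and their log2 values are noisy.

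The intensities were converted to log2 with no pseudocount and no further normalization. The 64 control probe sets were left out, which left 22626. Gene names came from the platform annotation, and looking up its Entrez identifiers among RefSeq genes changed 0 symbols. Of the probe sets, 20380 had 1 gene symbol, covering 12393 genes, 691 had several symbols and 1555 had none. Where a gene list needed 1 value per gene, the probe set with the highest mean level was used. The level of 1 probe set is not set against that of another, because probe sets differ in binding.

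With 1 group, the test across genes was of spread. The variance of each probe set between the 4 mice was compared with a prior variance that follows mean level, fitted robustly with limma 3.58.1 in R 4.3.3. The upper-tail F p-value was adjusted by the Benjamini-Hochberg method over all probe sets, with a threshold of 0.05. An SD from 4 arrays has a 95% interval from 0.57 to 3.73 times its value, so the number of arrays limits the precision. On simulated data with the real means and prior, 2 of 50 probe sets whose SD was multiplied by 4 passed, as did 18 of 50 at 8 times, 31 of 50 at 16 times and 40 of 50 at 32 times. In that simulation 6 of the unchanged probe sets passed.

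Before the data were examined, 29 gene lists were fixed, 17 of pathways and 12 of cell types or neighbouring tissues, and 479 of their 548 entries were measured. For each list and mouse, the median over members of that mouse minus the mean of the other 3 mice was computed. Its percentile was taken among 10000 random lists of the same size, drawn with replacement within 20 bins of mean level. The same was done for the median ratio of each member's SD to the prior SD at its level, called the relative spread. Genes are not replicates, so these percentiles describe these 4 arrays and are not p-values. A list was said to stand apart when it lay outside the central 95% of random lists. In lists of randomly drawn genes, 9 of 116 list and mouse pairs lay outside that range. When such lists were shifted by 0.5 log2 in mouse 1, 28 of 29 lay above it.

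The genes named follow a rule fixed at the same time. They are Abca1, the 25 genes with the largest SD among those past the test, and in each list the 2 members with the largest SD and the 1 with the smallest. If fewer than 25 passed, the rest were to be filled by relative spread and described as not past the test. Other list members are named where they passed when adjusted over the list alone, and were chosen after their values were seen. The rule held 1 more gene, which is not reported here.

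After the data were seen, a further test was added for the 4956 genes with at least 2 probe sets. It compared the difference between mice that a gene's probe sets share with their disagreement, using limma's moderated variance and an F-test, adjusted by the Benjamini-Hochberg method. Probe sets of 1 gene on 1 array share the RNA and the hybridization, so this test separates a consistent difference from probe set noise and not animal from array. On simulated data, 0 of 50 genes with an SD between mice of 0.25 log2 passed, 8 of 50 at 0.5, 24 of 50 at 1 and 42 of 50 at 2.

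Alternatives were quantile normalization over again, a shift of the arrays to the same median, filters on low levels, leaving out probe sets whose identifiers end in _s_at or _x_at, other forms of the prior, unmatched random lists, list means, means over a gene's probe sets, a stricter threshold of 0.01, and leaving out each mouse in turn. A stronger filter on low levels and a signal floor of 64, under which signals are set to 64, were added after the data were seen. Python 3.11.15 with numpy, pandas and scipy 1.17.1 was used for the lists.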

Results

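Gene expression was measured in the liver of 4 ABCA1-transgenic male mice on a C57BL/6 background, with 1 array per mouse. ABCA1 is the membrane transporter that moves cholesterol and phospholipid to apolipoprotein A-I. The median signal over all probe sets was 278 in mouse 1, 302 in mouse 2, 305 in mouse 3 and 267 in mouse 4. The design addressed the effect of ABCA1 overexpression against wild-type liver. Only transgenic arrays were analysed here, so the comparisons below are between the 4 transgenic mice.

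Abca1, the gene overexpressed by design, was measured by 3 probe sets, and each varied little between the transgenic livers. The log2 signal was 12.82 ± 0.17 (SD, n = 4) on 1 probe set, and 8.87 ± 0.24 and 8.06 ± 0.25 (SD, n = 4) on the others. The highest and lowest mouse differed by 1.25-fold, 1.41-fold and 1.46-fold, respectively. On the first the lowest value, 12.67, was in mouse 1 and the highest in mouse 4. When 1 mouse was left out the SDs ran from 0.14 to 0.19, from 0.16 (without mouse 1) to 0.29 and from 0.13 (without mouse 3) to 0.30. With all mice they were 1.07, 0.99 and 0.82 times the prior SD at the same level, and limma's test of excess spread gave adjusted p of 0.979, 0.981 and 0.988. The labels do not name the species of the transgene, so it is open how far these mouse probe sets read it, and no level without the transgene was at hand.

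Levels were close between the mice for most genes. The median SD between mice was 0.30 log2 over all 22626 probe sets, from 0.15 for mean levels above 11.61 to 0.90 for mean levels of 4.53 to 5.76. Pairs of arrays differed by a median of 0.28 to 0.35 log2, with Pearson's r across probe sets of 0.950 to 0.959. After adjustment over all probe sets, 0 passed limma's test of excess spread. An unadjusted p under 0.05 was found for 839, where a well-fitting prior gives 1131.3. The prior was fitted to these same variances, so these counts do not measure how close the mice were. A prior fitted without robust estimation also gave 0, with 921 at an unadjusted p under 0.05. The 25 genes named by relative spread therefore did not pass, and their values are descriptive. Of these 25, 17 had their lowest level in mouse 1 and 14 their highest in mouse 2. They included genes of striated muscle (Myh1, Mb, Tnnc2, Acta1, Tnni2, Myot, Ckmt2 and Ttn) and of the exocrine pancreas (Cela3b, Prss2, Cpb1 and Ctrl). Others were Dmbt1, Krt4, a keratin of squamous epithelium, and the liver genes Cyp4a14, Aacs, Hsd3b5 and Moxd1. Among the 16969 probe sets of highest mean level, tested alone, 6 passed, for Myh1 (2 probe sets), Mb, Tnnc2, Dmbt1 and a group of pancreatic amylase genes.

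Most cholesterol synthesis genes lay on the same side of the other mice within each mouse. Their median was 0.57 log2 (1.48-fold) above the other 3 mice in mouse 3, with 20 of 20 members higher, and 0.45 (1.37-fold) above in mouse 2, with 18 of 20 higher. It was 0.41 below in mouse 1, with 1 of 20 members higher, and 0.50 below in mouse 4, with 0 of 20 higher. Each of these 4 values lay beyond all 10000 random lists, whose central 95% ran from -0.11 to 0.16 for mouse 3. Sqle, squalene epoxidase, measured 9.71, 11.57, 11.56 and 10.40 log2 in mice 1 to 4, and Mvk, mevalonate kinase, 6.45, 8.16, 9.03 and 7.79. Ebp, a sterol isomerase, had the smallest spread in the list, at 13.75 ± 0.10 (SD, n = 4). Sqle and Dhcr7, the last enzyme of the pathway, passed limma's test when adjusted over the list alone (adjusted p = 0.024 for both), and 0 members passed over all probe sets. The signs held when 1 mouse was left out, and the sizes moved: in mouse 1 the value was -0.26 without mouse 3 and -0.74 without mouse 4, in mouse 2 it was 0.74 without mouse 3 and 0.26 without mouse 4, and in mouse 4 it was -0.76 without mouse 1, -0.33 without mouse 2 and -0.31 without mouse 3. Markers of other tissues and cells moved in the same mice. In mouse 1 skeletal muscle was at -2.40, bile duct at -1.35 and exocrine pancreas at -0.70, the 3-prime to 5-prime ratios of the Gapdh, Actb and Pcx control probe sets were the lowest and the 18S signal was the highest. In mouse 2 pancreas was at 1.64, muscle at 1.27 and adipocytes at 0.49. In mouse 3 muscle was at 0.69, stellate cells at 0.30, adipocytes at -0.20 and pancreas at -0.38, and in mouse 4 muscle was at 0.98 and bile duct at 0.29. The muscle and bile duct values of mice 2 to 4 rested largely on mouse 1. Without mouse 1 muscle was at 0.27 in mouse 2, -0.48 in mouse 3 and 0.15 in mouse 4, and bile duct was at -0.32 in mouse 4.

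Fatty acid synthesis and fatty acid oxidation genes stood apart in mouse 3 with opposite signs. The synthesis list was 0.30 log2 higher in mouse 3 (99.99th percentile, 14 of 21 members higher) and 0.22 lower in mouse 1 (percentile 0.03). In mouse 4 it was 0.12 lower (percentile 0.53), a value of 0.02 when arrays were shifted to the same median and of -0.0079 without mouse 3. Srebf1, the transcription factor that drives lipogenesis, measured 13.44 in mouse 3 against 11.54, 12.01 and 11.65 in mice 1, 2 and 4. Aacs, which makes acetoacetyl-CoA in the cytosol, measured 11.97 in mouse 3 and 9.37 in mouse 1. Srebf1, Aacs and Thrsp passed when adjusted over the list alone. The oxidation list was 0.22 lower in mouse 3 (percentile 0.01, 5 of 24 members higher), 0.16 higher in mouse 1 (percentile 99.97) and 0.16 higher in mouse 4 (percentile 99.81). Cyp4a14, a fatty acid hydroxylase and PPAR-alpha target, measured 14.08, 13.41, 11.78 and 13.55 in mice 1 to 4, and Acot3, an acyl-CoA thioesterase, 10.56, 10.32, 8.48 and 9.77. Cyp4a14, Acot1, Acot3 and Vnn1 passed when adjusted over the list alone, while Acadvl, a mitochondrial oxidation enzyme, measured 13.91 ± 0.04 (SD, n = 4). In both lists 0 members passed over all probe sets. Without mouse 3 the oxidation value of mouse 4 was 0.09, inside the range of random lists, and that of mouse 1 was 0.10, without mouse 4 that of mouse 1 was 0.25, and without mouse 2 that of mouse 3 was -0.34. Markers of other tissues and cells moved in the same mice. In mouse 3 muscle transcripts were 0.69 higher, pancreas transcripts 0.38 lower and stellate cell markers 0.30 higher. In mouse 4 muscle transcripts were 0.98 higher, bile duct markers 0.29 higher and macrophage markers 0.16 higher. Without mouse 1 the muscle value was -0.48 in mouse 3 and 0.15 in mouse 4, and the bile duct value of mouse 4 was -0.32. In mouse 1 muscle transcripts were 2.40 lower, bile duct markers 1.35 lower and the Gapdh 3-prime to 5-prime log2 ratio the lowest, at 1.67.

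**Figure D1:**
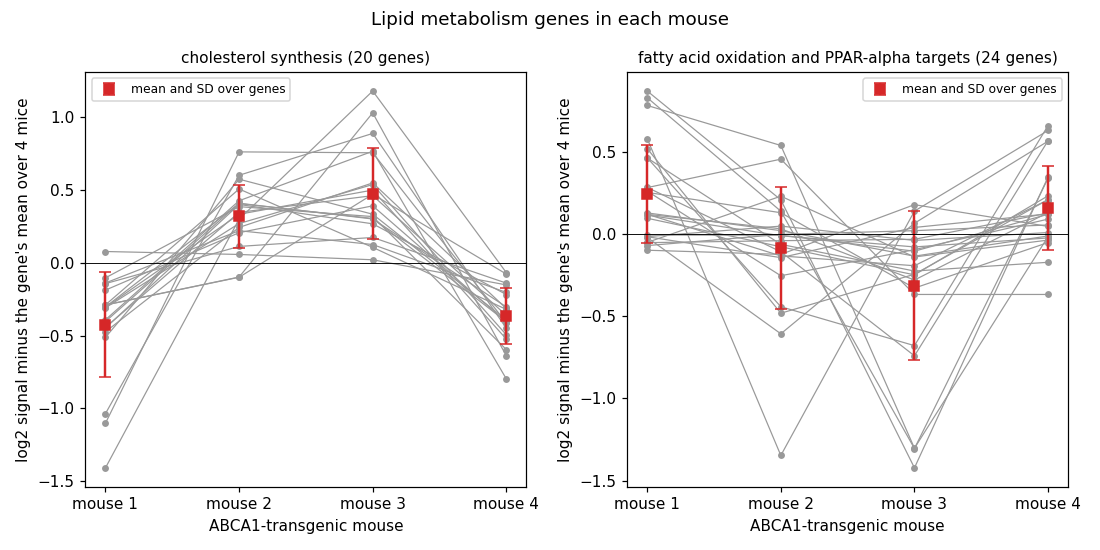
Log2 signal of each gene minus its own mean over the 4 ABCA1-transgenic mice (vertical axis) for the cholesterol synthesis list (20 genes, left) and the fatty acid oxidation and PPAR-alpha target list (24 genes, right). Grey lines are genes, and red squares with bars are the mean and SD over genes: cholesterol synthesis genes lie high in mice 2 and 3, whereas the oxidation genes lie lowest in mouse 3.

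Other lists of lipid handling lay inside the central 95% of random lists in each mouse. The lipoprotein list, which holds apolipoproteins and lipoprotein receptors, had 0 of 24 members with an unadjusted p under 0.05, and its relative spread of 0.98 lay at percentile 65.8. Lcat, the enzyme that esterifies plasma cholesterol, measured 13.57 ± 0.05 (SD, n = 4), and the widest members were Vldlr at 7.04 ± 0.37 and Lpl at 11.06 ± 0.34 (SD, n = 4). The list of LXR targets and sterol transport genes lay at percentile 89.7 for spread, and Srebf1, which it shares with the synthesis list, was its 1 member past the test when adjusted over the list alone. The bile acid list lay at percentile 20.1. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, measured 13.88 in mouse 3 against 12.80, 12.74 and 12.54 in mice 1, 2 and 4, and did not pass (adjusted p = 0.977, limma).

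Interferon response genes were 0.47 log2 lower in mouse 1, with 1 of 22 members higher, and 0.45 higher in mouse 3, with 19 of 22 higher. Both values lay beyond all 10000 random lists. Oasl2 measured 8.80 in mouse 1 and 10.87 in mouse 3, and Ifit2 6.77 and 8.45. Both are interferon-induced antiviral genes, whereas Iigp1 had the smallest spread, at 14.51 ± 0.13 (SD, n = 4). In this list 7 members had an unadjusted p under 0.05, 0 passed when adjusted over the list alone and 0 over all probe sets. Mouse 1 also had the lowest 3-prime to 5-prime ratio of the Gapdh control probe sets, a sign of RNA length, at 1.67 log2 against 1.94, 2.03 and 2.00 in mice 2 to 4, with muscle markers at -2.40 and bile duct markers at -1.35. In mouse 3 muscle markers were at 0.69 (-0.48 without mouse 1), stellate cell markers at 0.30, adipocyte markers at -0.20 and pancreas markers at -0.38.

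The ER stress and heat shock lists were lowest in mouse 3. The ER stress list was 0.28 lower there (4 of 21 members higher, below all random lists), 0.24 higher in mouse 2 and 0.19 higher in mouse 1. The medians of exocrine pancreas transcripts, at 1.64, and adipocyte markers, at 0.49, were also higher in mouse 2. Both medians were lower in mouse 3, at -0.38 and -0.20. Of adipocyte members 5 of 8 were higher in mouse 2 and 4 of 8 in mouse 3. In mouse 1 muscle was at -2.40, bile duct at -1.35 and pancreas at -0.70, with the lowest 3-prime to 5-prime ratios and the highest 18S signal. Creld2, an ER chaperone gene, measured 13.25, 13.33, 11.77 and 12.17 in mice 1 to 4, and Ddit3 7.40 in mouse 3 against 8.72 to 9.04 in the others. The heat shock list was 0.35 lower in mouse 3 and 0.33 higher in mouse 2, with 4 and 12 of 15 members higher. Hsph1, an HSP110 chaperone, measured 12.22 in mouse 3 and 13.32 in mouse 2. In both lists 0 members passed when adjusted over the list alone, and 0 over all probe sets. In mouse 1 the ER stress value was 0.37 without mouse 2 and 0.09 without mouse 3, and in mouse 2 the heat shock value was 0.20 without mouse 3.

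Acute phase genes had a relative spread of 1.36 (percentile 99.9), and their median was 0.13 lower in mouse 4 (percentile 0.1, 12 of 25 members higher), a value of 0.0059 when arrays were shifted to the same median and of -0.028 without mouse 1. Saa2, serum amyloid A, measured 9.92 in mouse 1 and 8.47 to 8.72 in the others, and Lcn2 measured 10.56, 10.46, 8.93 and 8.54 in mice 1 to 4. The fibrinogen gene Fga measured 14.87 ± 0.02 (SD, n = 4). Male-biased liver genes had a relative spread of 1.66 (percentile 99.98), and 2 of 13 passed when adjusted over the list alone. These were Moxd1, which measured 11.76, 10.02, 12.11 and 8.97 in mice 1 to 4, and Hsd3b5, a steroid dehydrogenase, which measured 10.92, 11.96, 13.11 and 12.10. The male-biased list was 0.12 higher in mouse 3 (percentile 97.9). Female-biased genes lay at percentile 98.4 for spread with 0 of 10 past that test, and were 0.54 higher in mouse 4 and 0.36 lower in mouse 3. These became 0.32 in mouse 4 without mouse 1, 0.23 in mouse 4 without mouse 3 and -0.17 in mouse 3 without mouse 4. Their widest members, Cux2 and Sult3a1, had low mean levels of 5.11 and 4.00. Markers of other tissues and cells also moved in mice 3 and 4. In mouse 4 muscle was at 0.98, bile duct at 0.29 and macrophages at 0.16. In mouse 3 muscle was at 0.69, stellate cells at 0.30, adipocytes at -0.20 and pancreas at -0.38. Without mouse 1 muscle was at 0.15 in mouse 4 and -0.48 in mouse 3, and bile duct at -0.32 in mouse 4. The gluconeogenesis list (percentile 62.9), clock list (percentile 73.1), immediate early list (percentile 61.8), xenobiotic list (percentile 87.1) and cell cycle list (percentile 36.5) did not stand apart for spread. Of single mice in these, the gluconeogenesis list was 0.17 higher in mouse 2, where pancreas was at 1.64 and muscle at 1.27, and the clock and xenobiotic lists were 0.13 and 0.09 higher in mouse 1, where muscle was at -2.40, bile duct at -1.35, the 3-prime to 5-prime ratios the lowest and 18S the highest. Without mouse 4 the clock value was 0.083, and without mouse 2 the xenobiotic value was 0.14.

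Transcripts of skeletal muscle had the widest spread of the 29 lists, with a median SD of 4.22 times the prior. Mouse 1 lay 2.40 log2 below the other 3 mice (0 of 13 members higher), and 12 of 13 members had their lowest level there. Mouse 2 lay 1.27 above the others, mouse 4 0.98 and mouse 3 0.69. Mb, myoglobin, measured 3.90 in mouse 1 against 10.42, 9.46 and 10.15 in mice 2 to 4, and Tnnc2, fast troponin C, 4.16 against 9.70, 9.10 and 9.52. Casq1 had the smallest spread, at 8.52 ± 0.36 (SD, n = 4). When adjusted over the list alone 9 of 13 members passed, and 0 over all probe sets. With signals under 64 raised to 64 the value of mouse 1 was -2.01, and without mouse 1 the values were 0.27 in mouse 2, 0.15 in mouse 4 and -0.48 in mouse 3. Without mouse 2 they were 1.13 in mouse 3 and 1.53 in mouse 4. The 18S ribosomal RNA control probe sets averaged 9.95 log2 in mouse 1 and 8.98, 8.75 and 8.79 in mice 2 to 4.

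Transcripts of the exocrine pancreas were highest in mouse 2. Their median lay 1.64 log2 above the other 3 mice, 10 of 10 members had their highest level there, and the value exceeded all random lists. The list lay 0.70 lower in mouse 1 and 0.38 lower in mouse 3, and in mouse 4 its median was 0.02 and its mean -0.03. The value of mouse 4 is set against mice that include mouse 2, and mouse 4 was second highest in 6 of 10 members. The probe set of a group of pancreatic amylase genes measured 4.63, 11.54, 5.15 and 10.35 in mice 1 to 4. Cpa1, carboxypeptidase A, measured 2.29, 9.36, 3.35 and 6.24 in mice 1 to 4, and Cpb1 6.63, 9.55, 3.89 and 8.20, whereas Cela1 measured 9.90 ± 0.31 (SD, n = 4). When adjusted over the list alone 4 of 10 passed, and 0 over all probe sets. Probe sets of Cela3b differed in size, with 9.28 in mouse 2 and 8.14 in mouse 1 on 1 probe set and 10.87 and 5.28 on another. Without mouse 2 the value was -0.31 in mouse 1 and -0.03 in mouse 3, both inside the range of random lists. Without mouse 1 the value of mouse 3 was -1.07, without mouse 3 that of mouse 1 was -1.11, and without mouse 4 that of mouse 3 was -0.60.

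**Figure D2:**
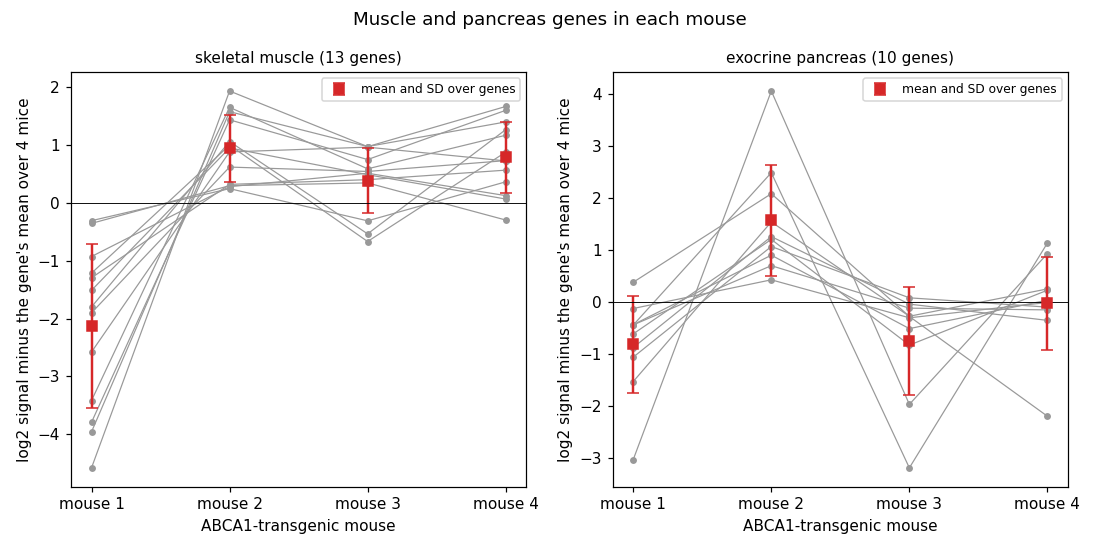
Log2 signal of each gene minus its own mean over the 4 ABCA1-transgenic mice (vertical axis) for the skeletal muscle list (13 genes, left) and the exocrine pancreas list (10 genes, right). Grey lines are genes, and red squares with bars are the mean and SD over genes: muscle genes lie low in mouse 1 and pancreas genes lie high in mouse 2.

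Bile duct markers were 1.35 log2 lower in mouse 1, with 0 of 9 members higher. Krt19, a keratin of biliary epithelium, measured 5.39 there against 8.41, 8.41 and 7.83 in mice 2 to 4. Krt19 and Cd24a passed when adjusted over the list alone, and the value was -0.40 with signals under 64 raised to 64. Mouse 1 also had skeletal muscle transcripts 2.40 lower, the lowest 3-prime to 5-prime log2 ratios of the Gapdh (1.67), Actb (1.82) and Pcx (4.09) control probe sets, and the highest 18S signal (9.95). Macrophage markers were 0.18 lower in mouse 2 and 0.16 higher in mouse 4, with Cd5l at 12.45 and 13.23, and 0 of 19 passed over the list alone. Without mouse 3 the value of mouse 2 was -0.10. The bile duct list was 0.29 higher in mouse 4, a value of 0.44 without mouse 2, 0.77 without mouse 3 and -0.32 without mouse 1. With signals under 64 raised to 64 it was 0 in mouse 4 (percentile 67.1), inside the range of random lists. The median of adipocyte markers was 0.49 higher in mouse 2 (percentile 99.1), with 5 of 8 members higher. It was 0.20 lower in mouse 3 (percentile 2.29), with 4 of 8 members higher. The mouse 3 value was -0.41 without mouse 1 and -0.08 without mouse 2. That value was 0.04 under the filter on low levels and 0.08 with means over each gene's probe sets. The widest members had opposite signs in mouse 2, with Cidea at -1.28 and Adipoq at 1.58 against the other mice. Car3 had the smallest spread, at 15.47 ± 0.11 (SD, n = 4), and was at -0.21 in mouse 2. Of adipocyte and stellate members 0 passed over the list alone, and stellate cell markers were 0.30 higher in mouse 3 (percentile 97.8). Hepatocyte markers did not stand apart in any mouse: their medians were -0.05, 0.08, 0.00 and -0.01 in mice 1 to 4, and Serpinc1, antithrombin, measured 15.17 ± 0.05 (SD, n = 4). The endothelial list (percentile 5.95 for spread) and the erythroid, lymphocyte, antigen-presenting cell and neutrophil lists (percentiles 33.6, 55.5, 73.1 and 90.6) had 0 members past the test over the list alone.

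Over all lists, 38 of 116 list and mouse pairs lay outside the central 95% of random lists, against 9 of 116 for lists of randomly drawn genes. Members of a list vary together, so the second number is not a test of the first. Of these pairs 10 were in mouse 1, 8 in mouse 2, 12 in mouse 3 and 8 in mouse 4. Of the 87 pairs that remain without mouse 1, 2, 3 or 4, respectively, 25, 31, 34 and 31 lay outside, against 28, 30, 26 and 30 of the same pairs with all mice. For spread, 12 of 29 lists lay above the central 95% of random lists, and 27 list entries in 8 lists passed limma's test when adjusted over their list alone.

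**Figure D3:**
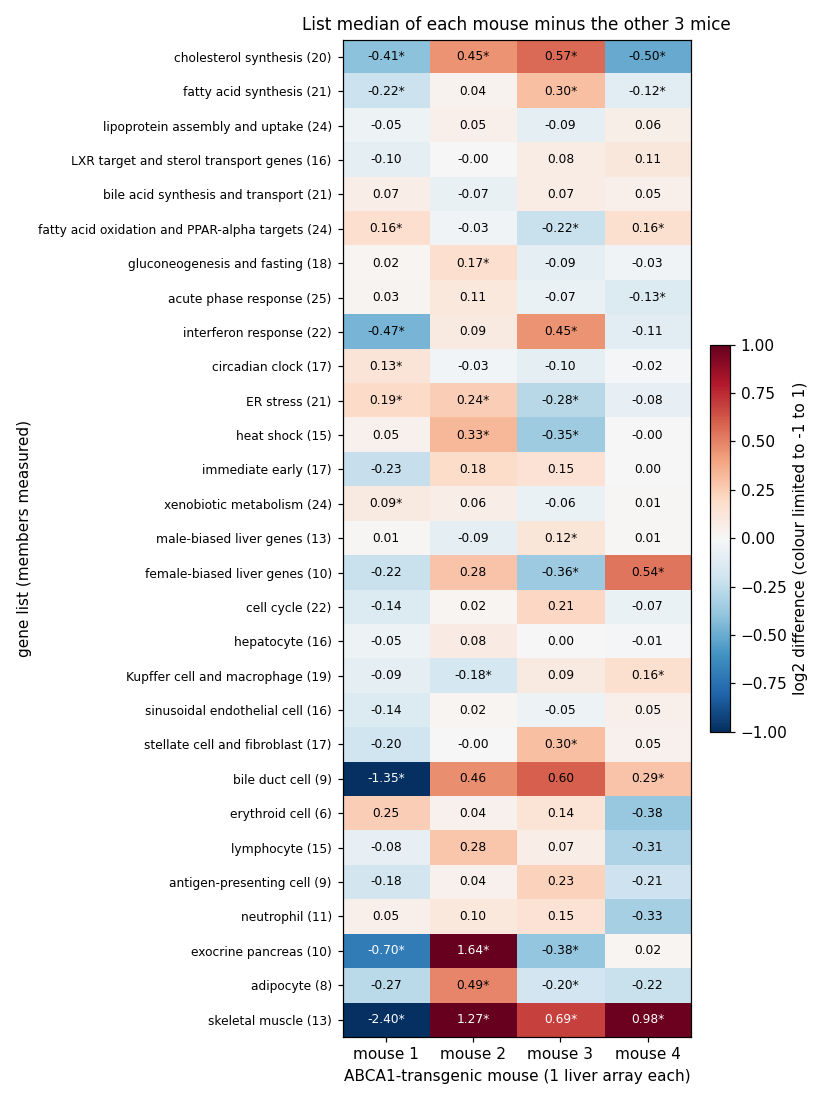
Median over list members of the log2 signal of each mouse minus the mean of the other 3 ABCA1-transgenic mice, for 29 gene lists (rows, with the number of members measured) and 4 mice (columns). The colour scale is limited to -1 to 1, and an asterisk marks the 38 values outside the central 95% of 10000 random lists of the same size and level. The muscle list ranges from -2.40 in mouse 1 to 1.27 in mouse 2, whereas hepatocyte markers stay between -0.05 and 0.08.

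Genes with several probe sets gave a test of differences between mice against probe set disagreement, added after the data were seen. Of 4956 such genes, 17 passed (limma, Benjamini-Hochberg). Mouse 3 was the lowest in 8 of the 17 and mouse 1 in 7. Cyp2b10, a xenobiotic-induced P450, had the smallest adjusted p (0.00078, limma) and lay 1.02 ± 0.08 (SE) below the gene's mean in mouse 3, and 0.60 and 0.46 above it in mice 2 and 1. Hmgcs1, the cytosolic HMG-CoA synthase, deviated by -0.32, 0.14, 0.41 and -0.22 in mice 1 to 4 (SE 0.07, 4 probe sets), and Thrsp, a lipogenic gene, by -0.65, 0.51, 0.49 and -0.35 (SE 0.08, 2 probe sets). The fatty acid transporter Cd36 deviated by 0.28, -0.08, -0.60 and 0.40 (SE 0.09, 3 probe sets). The heat shock genes Hspa1b and Hsph1 were lowest in mouse 3, at -0.56 and -0.58, and the interferon-induced gene Rsad2 was lowest in mouse 1, at -0.56. Ttn, titin of muscle, was lowest in mouse 1, at -3.02. The genes given here were chosen after their values were seen. Restricted to probe sets with a mean level over 7.5, 58 of 2752 genes passed, 16 of them among the 17. With arrays shifted to the same median 55 passed, and with signals under 64 raised to 64 only 1 passed. Without probe sets ending in _s_at or _x_at, 2 of the 4085 genes then tested passed. Leaving out 1 mouse left 0 genes (without mouse 3), 2 (without mouse 1), 4 (without mouse 2) and 2 (without mouse 4).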

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

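Of the tests in this part, the counts of extreme or lower members, the comparison of muscle with pancreas genes, the array scaling tests, the clock test and the values with a signal floor were chosen after the result was seen. The comparison of muscle with pancreas genes replaced one of log2 differences, written before its result was seen, because that one rested in part on signals under 64. In a group of 4, 1 mouse is set apart when its gap to the nearest other takes up more of the whole range than Dixon's 95% critical value, which chance gives in about 1 of 20 groups. This held for 12 of 107 named probe sets, 4 of 29 lists and 5.90% of all probe sets. Most named probe sets were picked by their spread in these same data, so their share does not test for an excess over 1 of 20.

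By this gap, mouse 1 was set apart from the other 3 mice for Mb (-6.11 log2 against their mean), Myh1 (-5.36), Tnnc2 (-5.28), Dmbt1 (-4.72), Myot (-4.64), Cftr (-4.04), Acta1 (-3.44), Myc (-1.63), Lpl (-0.67), Tef (0.13) and Edem1 (0.015). Mouse 3 was set apart for Cdk1, at 2.07. Some of these sizes rest on signals under 64, which are imprecise. With such signals set to 64 the value was -5.09 for Myh1, -4.01 for Mb, -3.44 for Tnnc2, -2.46 for Myot, -0.025 for Cftr and 1.58 for Cdk1, so these are lower bounds on the differences against this floor, and that of Cftr rests on signals under it. Among lists, mouse 1 was set apart for skeletal muscle (-2.40) and bile duct cells (-1.35), and mouse 2 for adipocytes (0.49) and bile acid synthesis and transport (-0.071).

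Skeletal muscle transcripts were low in mouse 1, and 12 of 13 list members had their lowest level there. Array scaling is argued against, since the value stayed at -2.24 after quantile normalization over again. Muscle tissue taken along with the liver pieces of mice 2, 3 and 4 is a candidate explanation that stays open: the count of 12 restates the pattern and does not test it, and 0 of the 13 genes are in another list. Faulty single probe sets stay open, because the 5 other probe sets of these genes had a median of -0.79, with 4 of 5 below 0, which does not decide. That 13 of 13 members were lower in mouse 1, with the list below all 10000 random lists, restates the pattern and does not test such faults. No biological explanation was tested, since the samples form 1 group.

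Exocrine pancreas transcripts were high in mouse 2, in 10 of 10 list members. Faulty single probe sets are argued against, since the median of 7 other probe sets of these genes was 3.61 above the other mice, with 7 of 7 above 0. For a single piece of neighbouring tissue that brought both the muscle and the pancreas transcripts, 1 ratio should be the same for all its genes if they rose from 1 baseline. This is the linear signal of mouse 3 above mouse 1, divided by that of mouse 2 above mouse 1. It had a median of -0.013 for pancreas and 0.65 for muscle genes (two-sided permutation p = 0.0008, members taken as independent), which goes against such a piece. The lists already lay on opposite sides in mouse 3, at 0.69 for muscle and -0.38 for pancreas, and the test was chosen after that was seen. The p therefore describes this difference and is not an independent test. Pancreas tissue in the piece of mouse 2 is a candidate explanation that stays open. The count of 10 restates the pattern and does not test it, and 0 of the 10 genes are in another list. Mouse 4 had the second highest level in 6 of the 10 members, and whether the same holds for its piece was not tested. No biological explanation was tested.

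Cholesterol synthesis transcripts differed between mice. Array scaling is argued against, since mouse 3 stayed 0.45 above the others and each mouse kept its sign after arrays were shifted to the same median. Dilution of liver RNA by other tissue as the whole cause is argued against, because hepatocyte markers were not lowered alike. Their medians were -0.05 in mouse 1 and -0.01 in mouse 4, against -0.41 and -0.50 for these genes. The two-sided permutation p was 0.0001 in mouse 1 and 2e-05, the smallest the permutations can give, in mouse 4. It takes members as independent, though members of a list vary together. The list was examined because it stood apart in these mice. The p therefore describes this difference and is not an independent test. Time of day or feeding at collection stays open, and the clock list cannot decide it. Its median was at percentile 98.7 in mouse 1 but inside the random range in mouse 4, at -0.023. A median can hide clock genes that move in opposite directions, as Per1 (-0.69) and Per2 (0.51) did in mouse 4. The list does not measure feeding. No biological explanation was tested, as the design gives none within the group.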

How the results depend on the processing

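The stronger filter on low levels (11313 probe sets kept), the signal floor, and the probe set agreement test with its settings were added after the data were seen. The median SD between mice, 0.30 log2, was 0.24 with the weaker filter (16969 kept), 0.19 with the stronger and 0.21 with the floor, and 0.27 to 0.29 when 1 mouse was left out. The count of probe sets with excess spread, 0, was 6 with the weaker filter, 11 with the stronger and 0 in each fit that left out 1 mouse, and the other fits also gave 0, while 7328 probe sets had a range of at least 1 log2 unit, a count without a test. The prior degrees of freedom were 4.82 without a filter, 6.57 and 7.88 with the weaker and stronger filter, and 0.77 with the floor. The filters also test fewer probe sets, and why the counts differ was not tested. The count of genes whose probe sets agree, 17, was 55 with arrays shifted to the same median, 1 with the floor and 0 to 4 when 1 mouse was left out. It was 2 without probe sets ending in _s_at or _x_at (4085 genes tested) and 58 over a mean level of 7.5 (2752 tested). The cause was not tested. The shift to the same median moved mouse 4 by 0.11 log2 and the other arrays by less. The 12 lists with excess spread numbered 9 to 13 when 1 mouse was left out, and 11 to 13 under the other alternatives. The 38 list and mouse pairs became 32 to 42 under other alternatives and 25 to 34 when 1 mouse was left out, where only 87 pairs remain, and 26 to 30 of the same pairs lay outside with all mice. Signs turned for fatty acid synthesis in mouse 4 (0.024) and acute phase genes in mouse 4 (0.0059) with arrays shifted to the same median, for adipocyte markers in mouse 3 with the weaker filter (0.036) and with means over a gene's probe sets (0.080), and without mouse 1 for bile duct markers in mouse 4 (-0.32, and up to 0.77 without another mouse) and muscle genes in mouse 3 (-0.48, and up to 1.13 without another mouse); the cause was not tested. The shift to the same median moves random lists alike, and both values stayed below the central 95% of them. Of the other values of these pairs, 16 with 1 mouse left out and 30 under other alternatives lay inside the random range with the same sign, and 96 and 232 lay outside it. The stronger filter and the signal floor are not part of these counts or of the turned signs above. The levels of Abca1 moved by less than 1 SD under each alternative run. No paired analysis was possible because the samples form 1 group.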

Other observations

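Gene families picked by symbol after the data were seen showed small shifts shared by many members. Respiratory chain subunits were 0.13 log2 higher in mouse 1 than in the other mice, with 53 of 74 members higher, above all 10000 random lists, and 0.12 lower in mouse 3 and 0.08 lower in mouse 4. Cytosolic ribosomal protein genes were 0.10 higher in mouse 1, 0.12 higher in mouse 2, 0.10 lower in mouse 3, and 0.12 lower in mouse 4, with 13 of 44 members higher there. Proteasome subunits were 0.11 higher in mouse 1, with 28 of 38 members higher, and 0.09 lower in mouse 4, with 7 of 38 higher. Mouse 1 also had the lowest 3-prime to 5-prime log2 ratio of the Gapdh, Actb and Pcx control probe sets, at 1.67, 1.82 and 4.09, and the highest 18S signal, at 9.95. When arrays were shifted to the same median the values of mouse 4 turned to 0.06 for the respiratory chain, 0.02 for the ribosome and 0.05 for the proteasome, while all stayed below the range of random lists. The values of mouse 1 were then 0.20, 0.17 and 0.18 for the 3 families, that of the ribosome in mouse 2 was 0.03, and in mouse 3 the respiratory chain was at -0.23 and the ribosome at -0.22. After quantile normalization over again the ribosome in mouse 3 was at -0.057 (percentile 3.9), inside the range of random lists. Complement and coagulation genes, which are secreted products of hepatocytes, varied less than random lists of their level, with a median log2 ratio of SD to the prior SD of -0.84 (percentile 0.01).

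The Y-linked gene Eif2s3y measured 10.79 ± 0.06 (SD, n = 4) and Uty 8.39 ± 0.12 and 8.72 ± 0.17 (SD, n = 4) on its probe sets in these male mice. Kdm5d, also Y-linked, measured from 5.57 ± 1.44 to 8.71 ± 0.08 (SD, n = 4) on 3 probe sets, and Xist 8.20 ± 0.09, 3.49 ± 1.68 and 3.01 ± 0.41 (SD, n = 4). Krt4 measured 11.24 in mouse 3 against 5.11, 5.90 and 4.74 in mice 1, 2 and 4, and the endothelial adhesion gene Vcam1 measured 9.88 in mouse 2 and 8.87 in mouse 4 against 5.72 and 5.89 in mice 1 and 3.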
